A study of Mus musculus with 2 samples.

How the data were processed

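Live splenic T cells (CD45 and CD3 positive; B220, Gr1 and Ter119 negative) of mice on a Western-type diet were sorted per the series design text. Per the labels' protocols, 50000 cells were sorted, 10000 were targeted on the Chromium Next GEM Single Cell 3′ v3.1 chemistry, and the cells of 4 mice of a genotype were pooled before the run. There are thus 2 libraries, 1 per genotype, and the group of each was taken from its genotype label. Per the submitters' processing notes the reads were processed with Cell Ranger 7.2.0 on the mouse build GRCm38. The annotation release, the intron setting and any further filter are not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger and kept for barcodes it called as cells, per the submitters' processing notes and the files' folder names. The files list 32285 genes, of which 78 symbols stand on more than 1 identifier. Positions come from GENCODE vM21 on GRCm38, matched by Ensembl identifier (131 of 131 named genes).

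Because each group is 1 library, no p-value, standard error or count of changed genes was computed, and cells were not used as replicates. UMIs were summed per library, or per library and class, and scaled to CPM by the total UMIs of the same cells. CPM have exact Poisson intervals, ratios exact conditional binomial intervals, shares of cells Clopper-Pearson intervals, and differences of shares Newcombe intervals, all at 95% and all for counting error only. A count of 0 was set to a floor of 3 counts for a bound on a fold. Beside a share of 0, the percentage that 3 cells would make is given, which is not a confidence limit. No fold is given where both libraries have 0. The depth, 8755401 UMIs in the KO library and 19788994 in the WT library before filters, left 4684745 and 17225641 UMIs in T cells, so a gene at 20 UMIs over both libraries was taken as measured (12356 genes). The median log2 ratio of all measured genes was 0.12 with this scaling, -0.02 with a median-ratio size factor and 0.04 with totals that leave out mitochondrial, ribosomal protein, immunoglobulin and T cell receptor segment genes.

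Cells were kept with 500 or more genes and at most 10% mitochondrial UMIs. In the KO library 138 barcodes missed the gene minimum and 1374 the mitochondrial limit, against 55 and 997 in the WT library, and a barcode can miss both. Scrublet, run per library through scanpy 1.11.5, called 10 KO barcodes (0.483%) and 0 WT barcodes, where the loading would give about 1.66% and 2.47%, so doublets cannot be taken as removed. Clustering used both libraries together and genes seen in 3 or more cells. Its steps were written with numpy, scipy, pandas and scikit-learn: counts per 10000, log1p, 2000 variable genes, scaling capped at 10, 30 principal components and 15 neighbours. Leiden ran at resolution 1 on the graph of shared neighbours (leidenalg 0.10.2, igraph 0.11.9). Ezh2, T cell receptor segments, immunoglobulin, hemoglobin, Xist and Y genes were left out of the variable genes. No integration was applied, since library and genotype are the same split. The 12 clusters were named from 19 fixed marker lists by mean log ratio against the other clusters, needing a score of 0.5 and 3 detected markers. The marker lists were fixed in advance, the score and its minimum were not. Clusters were called CD4 naive-like (clusters 0, 2 and 8), CD8-like (1, 3 and 4), CD4 memory or Tfh-like (5 and 7), Treg-like (6), NKT-like (9), gamma delta-like (10) and interferon-high (11). Other software was Python 3.11.15, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

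The groups, the comparisons, the filters, the marker lists, 28 gene lists and the rule for named genes were set before the data were examined. By that rule Ezh2 comes first. Genes with 50 CPM or more in 1 library and 20 or more UMIs over both were then ranked by ratio, taking the 10 highest and 10 lowest in all T cells and the 5 highest and 5 lowest in each class with 100 or more cells in both libraries. Immunoglobulin, hemoglobin, T cell receptor segment, mitochondrial, Xist, Tsix and Y genes were left out of the ranking and are given as groups. Each list gives up to 4 members of 10 CPM or more that are at least 1.5-fold apart, or else its most abundant members, and 14 cytokine and master regulator genes were always taken. Some genes this rule selects are not reported here. Malat1, given for the barcode states only, was chosen after the data were seen. The lists cover PRC2 subunits, Polycomb-repressed genes, naive, activated, Th1, Th2, Th17, Tfh, Treg, cytotoxic, inhibitory receptor, NKT and gamma delta T cell genes, cell cycle, interferon response, cholesterol and lipid handling, homing receptors, immediate early and heat shock genes, T cell receptor induced genes, apoptosis and p53, chromatin regulators, glycolysis, oxidative phosphorylation, sex-linked genes, and genes of B, myeloid, red or platelet and NK cells. A list's value is the median log2 ratio of its measured members, with an interval from 1000 Poisson resamples of the counts and its percentile among 10000 random lists matched in 20 bins of expression, which describes these libraries only.

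Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs and leaving out shallower cells. Other settings chosen in advance were looser (200 genes, 20% mitochondrial) and stricter (1000 genes, 5%) filters, called doublets kept, thinning, Leiden resolutions of 0.5 and 2, variable genes chosen per library, clusters from the markers alone, KO cells placed on WT clusters, UMI gates for CD4, CD8 and Treg cells, both other scalings, the mean of per-cell CPM, KO cells weighted to WT class shares, T cells by gate, list minima of 100 and 5 UMIs, and thinning to 1000 UMIs or not at all. Added after the data were seen were ribosome-rich and ribosome-poor cells taken alone (divided at 10% ribosomal protein UMIs), also with looser filters and with gates, barcodes over 30000 UMIs left out, clustering without genes 2-fold or more apart, and barcodes that failed the filters (those with 200 or more genes, without called doublets). Scripts were tested on simulated counts of 12386 genes for the comparison of all T cells, with 200 genes drawn to change and those with too few UMIs left out of the tally. The interval held the true ratio for 95.6% of 12189 unchanged genes and excluded no change for 81.6% of 49 genes at 1.5-fold, 96% of 50 at 2-fold, 100% of 50 at 4-fold and 83.3% of 48 at 0.5-fold. A list of 20 genes at 2-fold had a median of 1.03 at percentile 100, and 20 unchanged genes stood at percentile 46.3. All simulated counts were Poisson draws, as the intervals assume, so the test does not cover UMIs clumped in few cells.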

Results

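Spleen T cells of mice fed a Western-type diet were profiled by droplet single-cell RNA sequencing in 2 groups, one labelled Ezh2 KO (a knockout made with Cd4, as the labels write it) and one labelled wild type (WT). Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places a repressive methyl mark on histone H3. The series title links Ezh2 in T cells to their plasticity and to atherosclerosis, and the comparison asks which genes and T cell classes differ between the genotypes. Each group is 1 library made from the pooled cells of 4 mice, so no difference below has a replicate check. The library labelled Ezh2 KO (the KO library) held 2072 barcodes and 8755401 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule). The WT library held 3090 barcodes and 19788994 UMIs. Both are below the 10000 cells that were targeted. The median barcode held 2933 UMIs and 1519.5 genes in the KO library, against 4604 UMIs and 2102.5 genes in the WT library. Values are CPM, a gene's UMIs summed over cells and scaled to the total of the library or class, and a fold is the KO library's CPM over that of the WT library. The 95% intervals in brackets cover counting error only.

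RNA quality differed between the libraries. Mitochondrial genes took a median of 12.1% of a barcode's UMIs in the KO library and 5.42% in the WT library, and 656 of 2072 barcodes (31.7%) passed the cell filters in the KO library against 2051 of 3090 (66.4%) in the WT library. Barcodes also split into a state rich in ribosomal protein transcripts (10% or more of UMIs) and a state poor in them. Of the passing cells, 226 of 656 in the KO library (34.5%, 30.8 to 38.2) and 1475 of 2051 in the WT library (71.9%, 69.9 to 73.9) were ribosome-rich. The limit between the states is a range and not a boundary between types, since 50 KO cells (7.62%) and 74 WT cells (3.61%) lay between 8% and 12%. Ribosome-rich cells had median depths of 11577.5 and 9675 UMIs in the KO and WT libraries, and ribosome-poor cells 3221.5 and 3339.5. Malat1, a long RNA kept in the nucleus, took 4.55% of UMIs in ribosome-poor and 1.66% in ribosome-rich cells of the KO library, and 4.84% and 1.57% in the WT library. Gene levels are therefore also given within each state where the state moves them. In the KO library 7 barcodes held over 30000 UMIs, all of them CD8-like, and carried 15.7% of the UMIs of its T cells. In the WT library 10 barcodes did so, with 2.27%. The largest KO barcode held 286012 UMIs and 11188 genes, and such barcodes may hold more than 1 cell.

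Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341, minus strand, GRCm38) was detected in both libraries, with 136 UMIs in the KO library and 553 in the WT library. Its level was 29.0 CPM (24.4 to 34.3) in the KO library and 32.1 CPM (29.5 to 34.9) in the WT library, a fold of 0.904 (0.744 to 1.09). By class, it stood at 24.4 and 22.0 CPM in CD8-like cells, 42.8 and 20.3 CPM in CD4 naive-like cells and 55.8 and 83.8 CPM in CD4 memory or Tfh-like cells of the KO and WT libraries. Only the CD4 naive-like fold, 2.11 (1.33 to 3.24), had an interval that excluded 1. Most KO cells of that class were ribosome-poor, a state with more Ezh2 in both libraries, and in conventional CD4 cells split by state the fold was 1.01 (0.571 to 1.68) in ribosome-rich and 0.998 (0.640 to 1.53) in ribosome-poor cells. The fold in all T cells turned above 1 once every cell was thinned to one depth, with a log2 ratio of 0.38, and in the barcodes that failed the filters, with 0.20. It also lay just above 1 under looser filters (32.2 and 31.97 CPM) and with KO cells weighted to the class shares of the WT library (32.4 and 32.1 CPM). It was below 1 within ribosome-rich cells (0.778, 0.597 to 1.001), within ribosome-poor cells (0.805, 0.582 to 1.11) and without barcodes over 30000 UMIs (0.856, 0.689 to 1.06), so its direction is not settled. Reads of this 3′ chemistry lie near the end of the transcript, and the labels do not name the deleted exons, so the Ezh2 count checks neither label.

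Rankings of single genes here and below take only genes of 50 CPM or more in at least 1 library. In all T cells, the ranked genes that stood furthest apart were higher in the KO library and formed 2 groups, one highest in CD8 cells and one in innate-like cells. Efna5, an ephrin ligand, had 114 CPM in the KO library and 1.39 CPM in the WT library, a fold of 82.0 (54.5 to 129). Its 535 KO UMIs came from 103 cells, and 21 of its 24 WT UMIs from 1 cell. Osbpl6, an oxysterol-binding protein, was 24.8-fold higher (19.9 to 31.3) in the KO library, Tspan9, a tetraspanin, 18.3-fold (14.2 to 24.0), and Rasgef1b, a Ras exchange factor, 9.63-fold (8.01 to 11.6). A further 5 of the 10 highest genes led the NKT-like cluster. These were Epha3, an ephrin receptor (66.5-fold, 42.9 to 109), Akap6, a kinase anchoring protein (32.1-fold, 21.5 to 49.8), A330093E20Rik, annotated as an antisense RNA (18.5-fold, 14.1 to 24.7), Zbtb16, the transcription factor PLZF of innate-like T cells (14.8-fold, 12.3 to 18.1), and Klra1, a Ly49 receptor (12.4-fold, 9.60 to 16.1).

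Outside the NKT-like class the first group kept its folds, at 87.8 for Efna5, 26.6 for Osbpl6, 19.6 for Tspan9 and 9.89 for Rasgef1b. Those of the second group were smaller there, at 20.8 for Epha3, 9.19 for Akap6, 4.27 for Zbtb16, 4.28 for Klra1 and 1.65 (1.002 to 2.65) for A330093E20Rik. These rest largely on the KO barcodes over 30000 UMIs, all CD8-like: of the UMIs in CD8-like KO cells, only 9 of 109 for Zbtb16, 16 of 103 for Epha3, 6 of 58 for Akap6, 31 of 78 for Klra1 and 1 of 25 for A330093E20Rik lay in other barcodes. With cells gated by their Cd4 and Cd8 UMIs and not by clusters, Osbpl6 had 195 CPM in the CD8 gate and 46.7 CPM in the CD4 gate of the KO library. Zbtb16 had 16.8 and 187 CPM, and Epha3 6.52 and 132 CPM. The median log2 ratio of the 10 genes was 4.42 in all T cells, 4.39 in ribosome-rich cells and 4.61 in ribosome-poor cells, and each of the 10 was higher in the KO library in both states. Single folds moved with the state: Zbtb16 was 24.0-fold higher in ribosome-rich and 4.21-fold in ribosome-poor cells, and Rasgef1b 14.3- and 2.90-fold. For Efna5 the folds were 66.1 and 297, but its few WT UMIs, most of them from 1 cell, cannot set these apart. Efna5 lies on chromosome 17 (62604184 to 62881317, minus strand), Epha3 on chromosome 16 (63543534 to 63864175, minus strand), Osbpl6 on chromosome 2 (76406508 to 76600647, plus strand) and Zbtb16 on chromosome 9 (48654297 to 48836222, minus strand).

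The 10 ranked genes lowest in the KO library included 2 of the naive T cell list and 3 of the interferon list. Igfbp4, an IGF-binding protein of naive T cells, had 31.6 CPM in the KO library and 251 CPM in the WT library, a fold of 0.126 (0.106 to 0.148). Dapl1, a marker of naive and memory CD8 cells, had 97.8 and 399 CPM (0.245, 0.223 to 0.270), and Ly6a, the interferon-induced surface protein Sca-1, 94.6 and 332 CPM (0.285, 0.258 to 0.314). Ifi27l2a, an interferon-induced gene, stood at 0.391 (0.368 to 0.414), and Gbp2, a guanylate-binding protein, at 0.432 (0.349 to 0.529). Ly6c1 stood at 0.397 (0.325 to 0.481) in all T cells but was higher in CD8-like cells, by 3.49-fold (2.14 to 5.77). Purb stood at 0.470 (0.410 to 0.538) and Selenop at 0.488 (0.415 to 0.570). The ribosomal protein gene Rpl9 (0.328) and Gstp1 (0.370) have near-identical copies in the genome, and their levels are uncertain. All 10 were lower in the KO library in both states, with median log2 ratios of -1.12 in ribosome-rich and -1.17 in ribosome-poor cells. The Igfbp4 fold was 0.145 in ribosome-rich and 0.302 in ribosome-poor cells. Differences in the make-up of the classes, given below, can move such genes of naive T cells. Igfbp4 lies on chromosome 11 (99041244 to 99054392, plus strand), Dapl1 on chromosome 2 (59484653 to 59505020, plus strand) and Ly6a on chromosome 15 (74994877 to 74998031, minus strand).

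**Figure D1:**
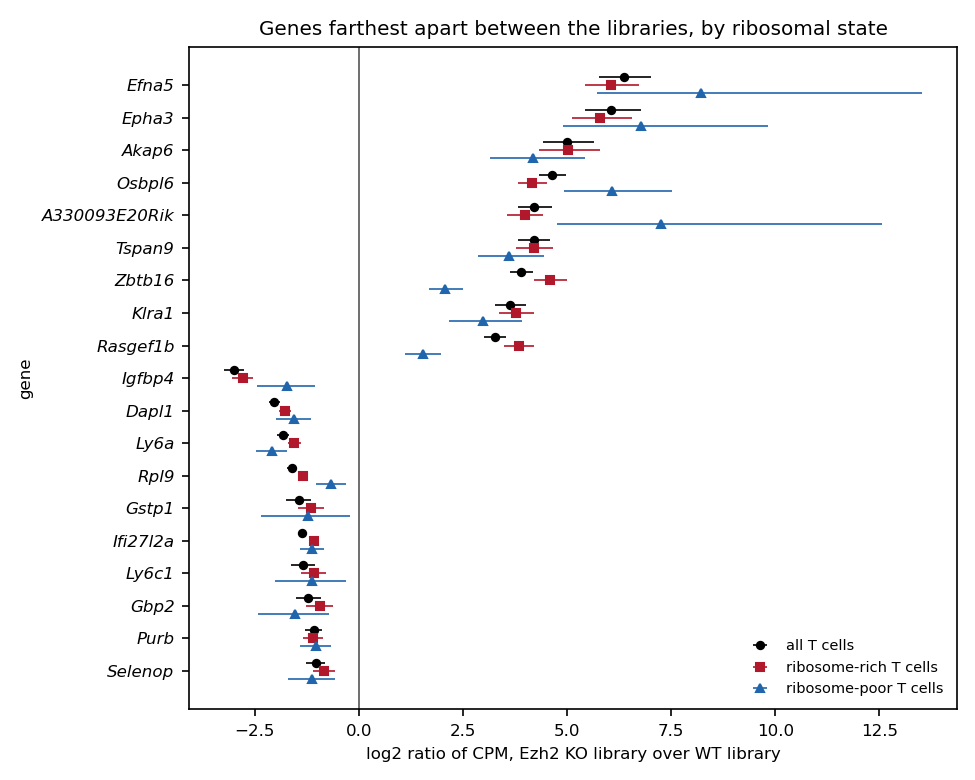
Named genes are plotted by their log2 ratio of CPM, Ezh2 KO library over WT library, within ribosome-rich and ribosome-poor cells, each point being the UMIs summed over the cells of 1 library set against the other. Genes from the 10 highest of all T cells lie to the right of 0 in both states, where the 10 have medians of 4.39 and 4.61, and the 10 lowest to the left, with medians of -1.12 and -1.17.

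Among the lists of T cell types, those of innate-like, gamma delta and cytotoxic T cells had the highest medians. The NKT and innate-like list had a median log2 ratio of 1.08 (0.80 to 1.31, percentile 100 of 10000 random lists matched on expression), with 11 of 19 measured members at least 1.5-fold higher in the KO library, 1 lower and 7 within. Its examples include Klra3, a Ly49 receptor, at 11.2-fold (8.10 to 15.7), and Ifitm10 at 3.99-fold (3.37 to 4.73). The median was 1.5 in ribosome-rich cells and -0.21 in ribosome-poor cells, and 0.62 (0.39 to 0.87) outside the NKT-like class. The cytotoxic and effector CD8 list had a median of 0.54 (0.39 to 0.63, percentile 100), with 11 of 23 members higher, 6 lower and 6 within. The granule protease Gzmm was 5.6-fold higher (4.71 to 6.67), Eomes, a transcription factor of memory CD8 and NK cells, 4.01-fold (3.48 to 4.61), and the chemokine Xcl1 3.33-fold (2.74 to 4.05). This median was 0.72 in ribosome-rich and 0.09 in ribosome-poor cells. The different make-up of the CD8-like class in the libraries, given below, can move it. The gamma delta list stood at 0.61 (0.52 to 1.12, percentile 99.9), with 8 of 12 members higher and 4 within, and turned to -0.59 in ribosome-poor cells. Its constant-region gene Tcrg-C2 was 5.94-fold higher (4.78 to 7.40), and the near-identical Tcrg genes can share reads.

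The helper T cell lists are given next to a median of 0.12 for all measured genes. Th1 genes had a median of 0.27 (0.21 to 0.41, percentile 90.7), 7 of 18 members higher, 3 lower and 8 within. The IL-18 receptor chain Il18rap was 2.11-fold higher (1.79 to 2.49), Tbx21, the Th1 master regulator T-bet, 1.92-fold (1.69 to 2.19) and Stat4, which signals for IL-12, 1.90-fold (1.82 to 1.98). The Th1 median was -0.12 in ribosome-poor cells, 0.12 in thinned cells and 0.0830 with KO cells weighted to the class shares of the WT library. Th2 genes had a median of 0.23 (0.02 to 0.54, percentile 68.0; ribosome-poor -0.04), with 3 of 11 members higher, 2 lower and 6 within. Il17rb, the IL-25 receptor, was 28.7-fold higher (15.3 to 59.7) in the KO library, or 13.6-fold outside the NKT-like class, and Il4ra 1.56-fold (1.39 to 1.74). Gata3, the Th2 master regulator, had 71.1 and 62.3 CPM (1.14, 1.01 to 1.29), and turned to a log2 ratio of -0.04 in ribosome-poor cells. The Th17 median was -0.07 (-0.25 to 0.09, percentile 12.4), with 2 of 12 higher and 10 within. Stat3 was at 1.03 and Batf at 0.984. The Tfh median was 0.10 (-0.03 to 0.17, percentile 46.0), with 2 of 15 higher, 5 lower and 8 within. The B-follicle homing receptor Cxcr5 was 1.86-fold higher (1.58 to 2.19), Bcl6, the Tfh master regulator, 1.41-fold (1.23 to 1.62), and Cd200 lower at 0.502 (0.364 to 0.678).

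Lists that stood lower in the KO library included those of regulatory T cells, proliferation, interferon response and T cell receptor signalling. The Treg list had a median of -0.88 (-1.09 to -0.59, percentile 0), with 12 of 20 members lower, 1 higher and 7 within. Interferon response genes had a median of -0.45 (-0.54 to -0.36, percentile 0), with 11 of 33 lower and 22 within, and stood at -0.33 in ribosome-rich and -0.56 in ribosome-poor cells. The cell cycle list was at -0.58 (-0.70 to -0.36, percentile 0), with 11 of 22 lower, 1 higher and 10 within, and -0.18 in ribosome-poor cells. The chromatin protein Hmgb2 stood at 0.634 (0.577 to 0.696) and the tubulin Tubb5 at 0.702 (0.662 to 0.744). Genes induced by the T cell receptor had a median of -0.36 (-0.47 to -0.02, percentile 0.010), with 8 of 21 lower, 3 higher and 10 within. Among them Il2ra, the IL-2 receptor alpha chain, stood at 0.408 (0.300 to 0.544), Tnfrsf9 at 0.518 (0.398 to 0.665) and Ikzf3 at 1.65 (1.56 to 1.74). Weighting KO cells to the class shares of the WT library moved that median to 0.01. The inhibitory receptor list was at -0.23 (-0.66 to -0.06, percentile 0.600), with 6 of 16 lower, 3 higher and 7 within, of which Lag3 stood at 0.287 (0.173 to 0.453). In ribosome-poor cells the inhibitory receptor median was -1.04.

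**Figure D2:**
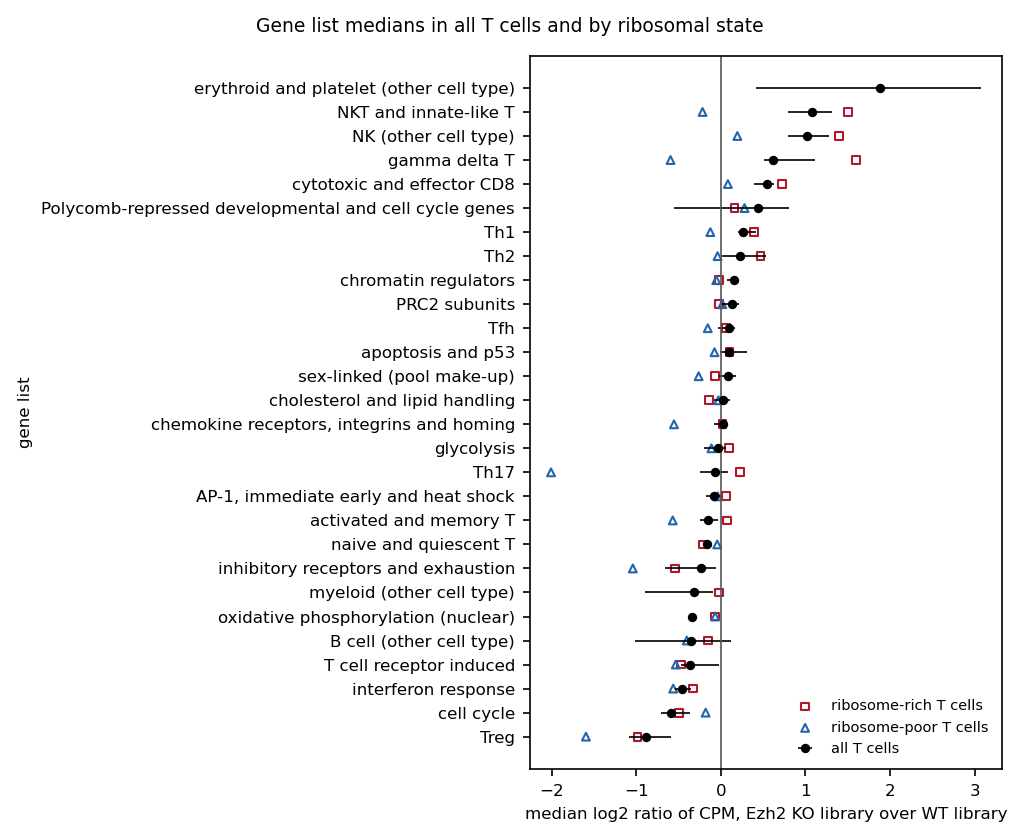
Each gene list is shown on the vertical axis with the median log2 ratio of its measured members, Ezh2 KO library over WT library, on the horizontal axis. Black points are all T cells with lines for the interval from resampling the counts, red open squares ribosome-rich cells and blue open triangles ribosome-poor cells; the Treg list lies left of 0 in all 3 (-0.88, -0.98 and -1.59), while the NKT list lies at 1.08, 1.5 and -0.21.

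PRC2 subunits and other chromatin genes lay close to the median of all genes, which itself stood at a log2 ratio of 0.12 under this scaling. The PRC2 list had a median of 0.14 (0.01 to 0.21, percentile 51.9), with 1 of 11 members higher and 10 within, and -0.02 in ribosome-rich cells. Its member Jarid2 was 1.58-fold higher (1.47 to 1.69), while Suz12 stood at 1.42 (1.30 to 1.55) and Rbbp4 at 0.965 (0.879 to 1.06). Chromatin regulators were at 0.16 (0.08 to 0.21, percentile 69.0), with 29 of 31 within 1.5-fold and 2 lower, and turned to -0.02 and -0.05 in ribosome-rich and ribosome-poor cells. Nsd1 stood at 1.32 (1.25 to 1.39). Of 35 developmental and cell cycle genes known as Polycomb targets, 5 had enough UMIs, with a median of 0.44 (-0.55 to 0.80, percentile 87.0) and 4 of the 5 within 1.5-fold. Lmo4 was 1.79-fold higher (1.54 to 2.07) and Cd9 at 0.700 (0.593 to 0.822), and the median was -0.30 without the barcodes over 30000 UMIs. The naive T cell list had a median of -0.16 (-0.20 to -0.11, percentile 7.51), with 3 of 19 lower, 1 higher (Txk, 1.81, 1.72 to 1.90) and 15 within. The activated and memory list was at -0.15 (-0.25 to -0.03, percentile 0.930), with 5 of 25 higher, 2 lower and 18 within, and turned to 0.08 in ribosome-rich cells. Its adhesion receptor Cd44 was 1.86-fold higher (1.69 to 2.06), Il2rb 1.88-fold (1.73 to 2.04), and the integrin Itga4 lower at 0.561 (0.525 to 0.599).

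Some BCL2 family genes, of both survival and death, were higher in the KO library over all T cells. Bcl2 had 938 CPM in the KO library and 462 CPM in the WT library (2.03, 1.957 to 2.11), Bcl2l1, which encodes BCL-XL, was 2.12-fold higher (1.80 to 2.495), and the death-promoting members Bcl2l11 and Bbc3 were 1.85- and 1.87-fold higher. In NKT-like cells, with only 11 in the WT library, Bcl2 was lower at 0.195 (0.145 to 0.264). The whole apoptosis and p53 list had a median of 0.09 (percentile 41.2), with 7 of 19 higher, 1 lower and 11 within. Cholesterol and lipid handling genes were alike in the libraries, at 0.03 (-0.08 to 0.11, percentile 17.0), with 25 of 26 within 1.5-fold and 1 higher. Of these the sterol exporter Abcg1 stood at 1.04 (0.929 to 1.15) and Mylip, which degrades the LDL receptor, at 1.41 (1.26 to 1.57). Homing receptors and integrins were at 0.02 (-0.08 to 0.08, percentile 19.5), with 5 of 24 higher, 3 lower and 16 within. Immediate early and heat shock genes were at -0.08 (percentile 4.41), with 5 of 22 higher, 2 lower and 15 within, among them Jun at 1.90 (1.64 to 2.21) and Nfkbia at 0.655 (0.599 to 0.715). Nuclear genes of oxidative phosphorylation had a median of -0.34 (-0.38 to -0.30, percentile 0) with all 28 within 1.5-fold, and -0.07 in each state taken alone. The glycolysis median was -0.04 (percentile 9.66), with 16 of 17 within 1.5-fold and 1 higher. Its members Aldoa and Pkm stood at 0.672 (0.618 to 0.729) and 0.713 (0.660 to 0.769).

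Transcripts of other cell types were low in both libraries, and no cluster had the markers of a cell outside the T lineage. The smallest cluster held 31 cells, so a few cells of another type would not have been seen this way. B cell genes summed to 203 CPM in the KO library and 242 CPM in the WT library, with a list median of -0.35 (-1.01 to 0.12, percentile 2.11). Myeloid genes summed to 131 and 152 CPM, with a median of -0.32 (-0.89 to -0.10, percentile 4.79). Red cell and platelet genes had a median of 1.88 (0.42 to 3.07, percentile 99.7) over 3 measured genes, and all hemoglobin genes summed to 42 KO and 19 WT UMIs, or 8.97 and 1.10 CPM. NK genes stood higher in the KO library, at 180 and 68.8 CPM, with a median of 1.02 (0.79 to 1.28, percentile 100), 6 of 8 measured members higher, 1 lower and 1 within. The Ly49 genes Klra8 (93.8-fold, 42.1 to 259; 34 and 1 cells) and Klra4 (36.5-fold, 21.8 to 65.5) led the NK list. The Ly49 genes resemble each other closely and can share reads. Sex-linked genes were alike in the pools, with Xist at 2 and 1 UMIs, Ddx3y at 81.8 and 77.0 CPM, and a median of 0.09 (percentile 41.8). Immunoglobulin genes took 203 and 225 CPM, T cell receptor segments 337 and 288 CPM, Y genes 324 and 307 CPM, mitochondrial genes 4.84% and 3.59% of UMIs, and ribosomal protein genes 17.8% and 23.4%.

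Shares of T cell classes also stood apart. CD8-like cells made up 45.3% (41.4 to 49.2) of T cells in the KO library and 33.0% (30.9 to 35.0) in the WT library, a difference of 12.3 percentage points (8.02 to 16.6). This sum hides opposite differences inside the class. Cluster 1, which scored as naive CD8, held 16 KO and 379 WT cells. Clusters 3 and 4, which scored as memory or effector CD8, held 119 and 162 KO cells and 188 and 109 WT cells. Conventional CD4-like cells made up 40.1% (36.3 to 44.0) and 54.4% (52.2 to 56.6), a difference of -14.3 points. Of these, CD4 naive-like cells were 23.8% and 38.6% (-14.8 points), and CD4 memory or Tfh-like cells 16.3% and 15.8% (0.465 points, -2.64 to 3.85). Treg-like cells were 5.64% (4.00 to 7.69) and 9.56% (8.32 to 10.9), a difference of -3.92 points. NKT-like cells were 48 of 656 (7.32%, 5.44 to 9.58) and 11 of 2051 (0.536%, 0.268 to 0.958). Most Zbtb16 UMIs lay in this class in the KO library but in gamma delta-like cells in the WT library. The NKT-like share may therefore depend on how innate-like cells were divided between these classes. Gamma delta-like cells (0.762% and 1.32%) and interferon-high cells (0.915% and 1.22%) had differences whose intervals lay on both sides of 0.

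Several of these classes are led by genes that differ between the libraries, and clusters held mostly by 1 library may reflect that library. Clustered without the genes 2-fold or more apart, CD8-like cells were 46.5% and 32.4%, Treg-like cells 3.96% and 9.31%, and NKT-like cells 29 of 656 (4.42%, 2.98 to 6.29) and none in the WT library. The same clustering gave 34.9% and 39.6% CD4 naive-like cells and 8.08% and 15.6% CD4 memory or Tfh-like cells, so the split inside the CD4 cells is not settled. Keeping the 10 called doublets was enough to move the CD4 naive-like difference to -3.18 points. The CD8 difference was 3.66 points from marker genes alone and 6.38 points from UMI gates. Gated shares depend on the Cd4 level, those of CD8 cells too, since the CD8 gate leaves out cells with a Cd4 UMI. Cd4 was higher in the KO library in CD8-like cells (82.3 and 13.5 CPM, 30 and 39 cells) and NKT-like cells (198 and 19.9 CPM). It was about level in interferon-high cells (123 and 121 CPM). It was also higher in the KO library in each CD4 class. Cd4 had 1097 and 226 CPM in CD4 naive-like cells of the KO and WT libraries. It had 1366 and 395 CPM in CD4 memory or Tfh-like cells and 905 and 178 CPM in Treg-like cells. These classes differ in barcode state as well. Thinned to 2000 UMIs, 85.5% of KO and 36.4% of WT CD4 naive-like cells had a Cd4 UMI. Clusters of the WT cells alone held no NKT-like class, so placing KO cells on them could not find such cells and says nothing of their share. Within ribosome-rich cells the CD8 difference was 21.7 points, and the conventional CD4 difference was -28.2 points there and -6.44 points in ribosome-poor cells. For Treg-like cells the gated difference was -1.005 points (-2.09 to 0.434), and it turned to 0.242 points among ribosome-poor cells.

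**Figure D3:**
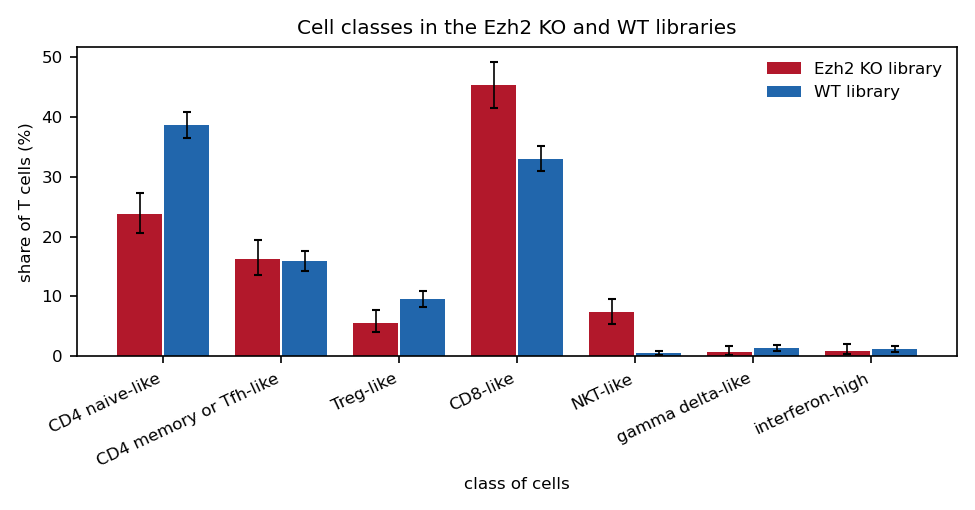
Bars give the share of T cells in each class (percent of passing cells) for the Ezh2 KO library (656 cells) and the WT library (2051 cells), with exact 95% binomial intervals that cover counting error only. CD8-like cells stand at 45.3% and 33.0%, Treg-like cells at 5.64% and 9.56%, and NKT-like cells at 7.32% and 0.536%.

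Within CD8-like cells, the KO library was again higher in Efna5 and Osbpl6 and lower in Igfbp4 and Dapl1. The class is not alike in the libraries: 379 of its 676 WT cells but 16 of its 297 KO cells lay in cluster 1, which scored as naive CD8, and the others in clusters 3 and 4, which scored as memory or effector CD8. Differences in genes of naive or memory cells can therefore come from this make-up. Cluster 4 has Osbpl6, Efna5, Rasgef1b and Tspan9 among its leading genes and none of the class's markers there. Cells may thus have been placed in the class partly by these genes. Efna5 had 147 and 3.33 CPM (44.1-fold, 29.0 to 70.2) and Osbpl6 177 and 10.4 CPM (17.0-fold, 13.3 to 22.1). The Ly49 receptor gene Klra4 was 21.6-fold higher (12.9 to 38.8), and Tspan9 15.002-fold (10.9 to 21.2). Eomes had 127 and 42.1 CPM (3.02, 2.59 to 3.53), Cd44 119 and 38.3 CPM (3.096, 2.64 to 3.64), Gzmm was 3.74-fold higher (3.098 to 4.53) and Stat4 2.004-fold (1.90 to 2.11). Cxcr5 was 2.85-fold higher (2.26 to 3.60), and the Tfh list stood at 0.70 (0.56 to 0.84, percentile 100), with 7 of 11 members higher and 4 within. Lowest were Igfbp4 (0.137, 0.105 to 0.175), Itgae, the integrin CD103 (0.141, 0.0929 to 0.207), Dapl1 (0.228, 0.203 to 0.254), the noncoding RNA 1700062C10Rik (0.319, 0.233 to 0.429) and Gbp2 (0.326, 0.242 to 0.431). Both states gave the same directions for Efna5 (37.8 and 113 in ribosome-rich and ribosome-poor cells), Eomes (2.86 and 4.51) and Itgae (0.161 and 0.0639).

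The interferon list stood at -0.40 (-0.50 to -0.30, percentile 0) in CD8-like cells, with 11 of 33 lower and 22 within, and the cell cycle list at -0.84 (-0.91 to -0.49, percentile 0), with 11 of 18 lower, 1 higher and 6 within. Cytotoxic genes, higher in all T cells, had a median of -0.10 (-0.34 to -0.04, percentile 1.86) here, with 3 of 23 higher, 8 lower and 12 within. The class held 297 KO and 676 WT cells, and 162 KO and 109 WT cells of it lay in cluster 4, which is nearly all ribosome-poor. The 7 barcodes over 30000 UMIs carried 24.0% of its KO UMIs, and leaving such barcodes out moved Igfbp4 to 0.0876, Itgae to 0.0718, Ly6a from 0.440 to 0.264, Klra1 from 2.31 to 1.17 (0.744 to 1.80) and Zbtb16 from 61.2 to 6.45 (1.80 to 28.7). It turned the gamma delta median of this class from 1.18 to -0.16 and the Treg median from 0.23 to -0.24.

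CD4 naive-like cells of the KO library were higher in several of the same genes and in Eomes, and lower in interferon and respiratory chain genes. Efna5 had 76 UMIs in 20 KO cells and none in the WT library, at least 261-fold higher against a floor of 3 counts. Growth hormone, Gh, had 32 and 1 UMIs (330-fold, 55.1 to 1.34e+04), which were not shown to be expression of the gene itself. Osbpl6 was 63.5-fold higher (26.6 to 184), the microtubule protein gene Map2 34.4-fold (17.7 to 71.9) and Tspan9 28.6-fold (17.3 to 48.9). Eomes had 46.1 and 7.51 CPM (6.14, 3.70 to 10.01), and Bcl6 72.5 and 35.5 CPM (2.04, 1.44 to 2.83). Lowest were Rpl9 (0.228), Igfbp4 (0.244, 0.191 to 0.308), Ly6a (0.257, 0.194 to 0.334), the proteasome assembly gene Psmg4 (0.272, 0.123 to 0.522) and the complex I gene Ndufa11 (0.315, 0.179 to 0.517). The interferon list stood at -0.58 (-0.70 to -0.36, percentile 0), with 16 of 33 lower, 2 higher and 15 within. Th1 genes stood at 0.68 (0.28 to 1.08, percentile 98.9), with 6 of 11 higher and 5 within, and cytotoxic genes at 1.02 (0.69 to 1.45, percentile 100), with 6 of 9 higher, 1 lower and 2 within. Oxidative phosphorylation stood at -0.75 (-0.82 to -0.62, percentile 0), with 17 of 28 lower and 11 within. Most KO cells of the class were in cluster 2 (126 of 156), which is mostly ribosome-poor, and most WT cells in cluster 0 (467 of 791). In conventional CD4 cells split by state, the oxidative phosphorylation median was -0.18 (ribosome-rich) and 0.04 (ribosome-poor) and the Th1 median 0.20 and -0.49, while the interferon median was -0.32 and -0.42.

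CD4 memory or Tfh-like cells of the KO library had lower levels of memory and Th1 genes, but also differed in barcode state and cluster. The calcium-binding protein genes S100a4 (11.2 and 277 CPM, 0.0403, 0.0131 to 0.0946) and S100a6 (64.7 and 589 CPM, 0.110, 0.0734 to 0.159) were among the lowest, with Gpm6b (0.105, 0.0449 to 0.208) and Sostdc1, a marker of Tfh cells (1 and 277 UMIs, 0.0198, 0.0005 to 0.111). Ralyl had 1 and 137 UMIs (0.0400, 0.00101 to 0.227) but a log2 ratio of 3.08 in the CD4 gate. Tbx21 stood at 0.179 (0.0713 to 0.376), and Il21, the Tfh cytokine, had 1 and 59 UMIs (0.0930, 0.00232 to 0.539). Ifng, the Th1 cytokine, had 0 and 37 UMIs, at least 2.25-fold lower. Il4 had 42.4 CPM (25.5 to 66.2) from 19 UMIs in 5 of 107 KO cells, and 10.6 CPM (6.91 to 15.5) from 26 UMIs in 14 of 325 WT cells. The shares of cells with an Il4 UMI were thus alike, and the intervals do not cover UMIs clumped in few cells. Highest were Zc3h12b (53.5-fold, 19.3 to 206), Osbpl6 (18.5-fold, 8.18 to 47.2), the ubiquitin-conjugating enzyme gene Ube2e2 (16.2-fold, 10.2 to 26.7), Auts2 (16.03-fold, 8.35 to 32.8) and the BMP receptor gene Bmpr1a (12.7-fold, 6.88 to 24.4). The activated and memory list stood at -1.32 (-1.53 to -1.13, percentile 0), with 16 of 23 lower, 1 higher and 6 within, and the Th1 list at -1.28 (-1.59 to -0.82, percentile 0), with 10 of 15 lower and 5 within. Glycolysis genes stood at -0.79 (percentile 0) and interferon genes at -0.72 (-0.83 to -0.46, percentile 0). Most KO cells were in cluster 7 (94 of 107, with 10 of the 94 ribosome-rich) and most WT cells in cluster 5 (249 of 325, with 212 of the 249 ribosome-rich). In conventional CD4 cells split by state, the activated and memory median was -0.32 (-0.56 to -0.13) in ribosome-rich and -0.38 (-0.62 to -0.15) in ribosome-poor cells, and the Th1 median 0.20 (-0.27 to 0.47) and -0.49 (-0.85 to -0.02). Within conventional CD4 cells, S100a4 was at 0.0997 in ribosome-rich and 0.141 in ribosome-poor cells, Gpm6b at 0.0501 and 0.173, Tbx21 at 0.367 and 0.308, S100a6 at 0.269 and 0.723, Zc3h12b at 2.32 and 2.75, and Ube2e2 at 6.31 and 2.92.

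Treg genes were lower in the KO library, both over all T cells and among the Treg-like cells themselves. Foxp3, the Treg master regulator (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), had 35 and 373 UMIs in all T cells (0.345, 0.237 to 0.489). The actin-capping gene Capg stood at 0.267 (0.201 to 0.347), Tnfrsf4, the co-stimulatory receptor OX40, at 0.296 (0.217 to 0.397) and Itgae at 0.340 (0.255 to 0.444). Itgae also led cluster 1, scored as naive CD8, which held 16 KO and 379 WT cells. Its fold over all T cells is therefore not particular to Treg cells. In Treg-like cells (37 KO and 196 WT cells) Foxp3 had 113 and 278 CPM (0.408, 0.225 to 0.683), Il2ra was at 0.431 (0.257 to 0.682), Tnfrsf4 at 0.38 (0.215 to 0.625) and Capg at 0.173 (0.0556 to 0.409). The Treg list stood at -0.49 (-0.87 to -0.32, percentile 0.5) there, with 10 of 20 lower and 10 within. Of these cells 11 of 37 KO and 101 of 196 WT cells were ribosome-rich, so the class differs in barcode state as well. Foxp3 and Il2ra are among the genes that define this class, so their levels inside it depend on which cells it takes in. Weighting KO cells to the class shares of the WT library moved the list's median in all T cells from -0.88 to -0.42. Thinned to 2000 UMIs, 1.85% (0.925 to 3.28) of KO and 4.56% (3.68 to 5.58) of WT T cells had a Foxp3 UMI. Without thinning it was 3.66% and 7.17%. In CD8-like cells, which should lack Foxp3, the thinned shares were 0 of 284 (3 cells would be 1.06%) and 0.151%, with median depths before thinning of 6329 and 10061 UMIs.

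NKT-like cells carried most of the Zbtb16 and much of the Il4 of the KO library. Zbtb16 had 416 of its 545 KO UMIs and Il4, the Th2 cytokine, 57 of its 93 KO UMIs in this class, with 32 of the Il4 UMIs in 1 cell. In the WT library, 109 Zbtb16 UMIs lay in gamma delta-like cells (22 of 27 cells, 603 CPM) and 16 in NKT-like cells. These classes may thus divide cells with Zbtb16 differently in each library. Zbtb16 is also a marker that names the NKT-like class, so its lead there was partly set in advance. Over all T cells Il4 was 11.4-fold higher in the KO library (7.48 to 17.8; 25 and 15 cells), and 5.45-fold (3.20 to 9.40) outside the NKT-like class. In the 48 KO cells of the class Zbtb16 had 1287 CPM, Epha3 832 CPM and Klra1 563 CPM, while in the 11 WT cells Zbtb16 had 318 CPM and Epha3 and Klra1 had no UMI. Gamma delta constant-region transcripts were present in the KO cells of this class too, with Tcrg-C2 at 297 CPM (26 cells) and Trdc at 186 CPM (8 cells), against 216 and 1262 CPM in gamma delta-like cells of the WT library. Tbx21 (210 and 378 CPM) was lower in the KO cells of the class than in its WT cells. So were Il2rb (105 and 676 CPM), Klrb1c (124 and 397 CPM) and Xcl1 (21.7 and 119 CPM), which are among the markers that name the class. Of its other markers, Zbtb16 and Klra1 were higher in the KO cells, and Cd160 was about level (189 and 199 CPM). The KO and WT cells of the class are thus not alike in its own markers. Thinned to 2000 UMIs (60 KO and 78 WT cells were shallower and left out), 6.21% (4.41 to 8.46) of KO and 0.963% (0.581 to 1.4998) of WT T cells had a Zbtb16 UMI, and 1.85% (0.925 to 3.28) and 0.203% (0.0553 to 0.518) an Il4 UMI. Without thinning the shares were 9.30% and 1.66% for Zbtb16, and 3.81% and 0.731% for Il4. In CD8-like cells the thinned shares were 0.352% and 0.301% for Zbtb16, and 0.352% and 0 of 664 (3 cells would be 0.452%) for Il4.

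Eomes was also seen in a higher share of KO cells, and Tbx21 only in some settings. After thinning, 12.6% (10.03 to 15.5) of KO and 3.04% (2.33 to 3.90) of WT T cells had an Eomes UMI (25.9% and 8.63% without thinning), and 10.2% (7.92 to 12.95) and 6.18% (5.16 to 7.34) a Tbx21 UMI (19.2% and 13.99%). In CD8-like cells the Eomes shares were 21.5% (16.8 to 26.7) and 6.93% (5.12 to 9.13), and the Tbx21 shares 15.1% (11.2 to 19.8) and 11.1% (8.85 to 13.8). Tbx21 was at 9.16% and 9.49% in ribosome-poor cells and at 3.03% and 12.3% in CD4 memory or Tfh-like cells. Thinned to 1000 UMIs, its shares of all T cells were 4.48% (3.02 to 6.36) and 3.29% (2.56 to 4.16). Treg-like cells, which should lack Eomes, had it in 0 of 31 KO cells (3 cells would be 9.68%) and 0 of 177 WT cells (3 cells would be 1.69%). Their median depths were 2714 and 4948 UMIs. For Tbx21 the background was taken in CD4 naive-like cells, at 0.763% and 0.133%, with median depths of 2872 and 8293 UMIs. Il21 was found in 0 of 596 thinned KO cells (3 cells would be 0.503%, not a confidence limit) and 0.558% of WT cells (0.152% and 1.37% without thinning). Over all T cells Il21 had 1 and 60 UMIs (0.0613, 0.00153 to 0.355). Its background in CD8-like cells was 0 of 284 and 0 of 664. Ifng had 11 and 61 UMIs (0.663, 0.315 to 1.27), a difference that was not detectable at this depth. Il13 had 9 UMIs in 1 KO cell and none in the WT library. Il5 and Il17a had no UMI, and Il10 had 1, in the WT library.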

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

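The tests in this part were chosen after the result was seen, except the weighting of KO cells to the class shares of the WT library, which was planned. Barcodes that failed the filters, taken with 200 or more genes and without called doublets (1395 in the KO library and 1038 in the WT library), lie outside the main comparison and were looked at apart. The 10 ranked genes highest in the KO library had a median log2 ratio of 4.83 there, against 4.42 in the passing T cells, and all 10 were higher in the KO library. Efna5 had 716 and 1 UMIs in these barcodes, Zbtb16 was 70.5-fold higher (32.2 to 193), and Igfbp4 lower at 0.264.

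The first pattern weighed is the height of these 10 genes, among them Efna5 and Epha3, in the KO library. A larger share of ribosome-poor barcodes is argued against as the whole cause, since the median log2 ratio was 4.39 within ribosome-rich cells. So are a few barcodes of very high UMI count, since it was 4.50 without those over 30000 UMIs. Both subsets are part of the cells from which the 10 genes were picked, so these medians are no independent check of the genes' height. Free RNA spread over all droplets would give like levels in the CD4 and CD8 gates of the KO library, but the 10 genes differed between the gates by a median of 2.93 on the log2 scale, 5 of them higher in each. A difference of library preparation or of the pooled mice cannot be told apart from the genotype, with 1 library per genotype. Loss of Ezh2, a repressor of transcription, may raise such genes, which stays an untested hypothesis.

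The second pattern is the lower Treg list, with a median of -0.88, which was smaller once class shares were evened: with KO cells weighted to the class shares of the WT library the median was -0.42 (-0.69 to -0.29). By bounds written before this value was seen, it would count against fewer cells as the whole cause below -0.4 and for it within 0.2 of 0; the interval spans the first bound and lies outside the second, so how much fewer cells explain stays open. For a time the second bound was used after the value was seen, which would have excluded this cause, and that reading was withdrawn. A larger share of ribosome-poor barcodes is argued against, since the median was -0.98 within ribosome-rich and -1.59 within ribosome-poor cells. Lower Treg gene levels per cell in the KO mice may add to it, since the list was also lower within Treg-like cells. These cells differ in barcode state between the libraries and are defined partly by the same genes, so that value cannot decide it. Library and mice stay open too.

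The third pattern is the smaller share of ribosome-rich barcodes in the KO library. The cell filters are argued against, since the share already differed by -30.8 percentage points over all barcodes (20.3% and 51.1%). Loss of cytoplasmic RNA from damaged cells is a candidate explanation: Malat1, kept in the nucleus, took a 2.74 times larger median share in ribosome-poor than in ribosome-rich KO cells, and 3.08 times in WT cells. Being alike in both libraries, these ratios describe the ribosome-poor state and do not show that KO cells were damaged more. Handling of 1 library and the genotype cannot be told apart as sources of the smaller share, with 1 library per genotype.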

How the results depend on the processing

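The tests on ribosome-rich or ribosome-poor cells alone, without barcodes over 30000 UMIs, without genes apart between the libraries, and on barcodes that failed the filters were chosen after the data were seen; the others were planned. Direction was counted only for results whose main interval excluded no change, which leaves out Ezh2 and the CD4 memory or Tfh share. Among such results, direction was kept in all settings by 83 of 107 named genes, 29 of 30 genes ranked within classes, 8 of 18 list medians, 3 of 5 class shares and 6 of 6 shares of cells with a UMI. By setting, 92 of 107 genes kept it in ribosome-poor cells and in failed barcodes, 104 in ribosome-rich cells and under stricter filters, 106 when thinned or under looser filters, and 107 under each other scaling, weighting or gate. The cause of the shifts below was not tested, and the small number of KO cells limits what each state can show.

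The CD8 difference (12.3 percentage points) was 28.7 under stricter filters, 3.66 from markers only, 6.38 gated, 21.7 in ribosome-rich cells and 19.6 there with looser filters. The conventional CD4 difference (-14.3) was -29.5 under stricter filters, -21.8 from markers only, -6.14 with KO cells placed on WT clusters, -28.2 in ribosome-rich cells, -6.44 in ribosome-poor cells and -24.5 in ribosome-rich cells with looser filters. The CD4 naive difference (-14.8) was -21.8 under stricter filters, -3.18 with doublets kept, -6.22 thinned, -3.78 at Leiden 0.5, -22.3 from markers only and also in ribosome-rich cells, -5.20 placed on WT clusters, -4.73 without genes apart and -7.92 in ribosome-poor cells. The CD4 memory or Tfh difference (0.465) was -7.75 under stricter filters, -11.4 with doublets kept, -8.47 thinned, -10.2 at Leiden 0.5, -7.47 without genes apart, -5.86 in ribosome-rich cells and -6.79 there with looser filters. The Treg difference (-3.92) was -1.005 gated, -10.4 in ribosome-poor cells, 0.242 gated in ribosome-poor cells and -1.31 in ribosome-rich cells with looser filters. The NKT difference (6.78) was 0 with KO cells placed on WT clusters, which is void because these held no NKT-like class, and 4.42 without genes apart.

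On the log2 scale, Ezh2 (-0.15) was 0.38 thinned and 0.20 in failed barcodes. The Th1 median (0.27) was 0.12 thinned, 0.12 with a median-ratio size factor, 0.18 with totals without mitochondrial, ribosomal, immunoglobulin and T cell receptor genes, 0.0560 as a mean over cells, 0.0830 weighted to WT class shares, -0.12 in ribosome-poor cells, 0.0342 in failed barcodes and 0.51 with members of 100 or more UMIs. Th2 (0.23) was -0.0375 in ribosome-poor cells and 0.56 in failed barcodes. Treg (-0.88) was -1.14 under looser filters, -0.42 weighted and -1.59 in ribosome-poor cells. The NKT list (1.08) was 0.80 under looser filters, 1.42 under stricter ones, 0.33 weighted, 1.5 in ribosome-rich cells, -0.21 in ribosome-poor cells and 0.46 in failed barcodes. PRC2 (0.14) turned to -0.00538 with a size factor, to -0.0122 under stricter filters and to -0.0199 in ribosome-rich cells, the activated list (-0.15) to 0.0766 in ribosome-rich cells, inhibitory receptors (-0.23) to 0.13 in failed barcodes, gamma delta (0.61) to -0.59 in ribosome-poor cells, T cell receptor induced genes (-0.36) to 0.0140 when weighted, chromatin regulators (0.16) to -0.0203 and -0.0526 in ribosome-rich and ribosome-poor cells, and oxidative phosphorylation (-0.34) to 0.0268 in failed barcodes.

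Single genes that turned direction in failed barcodes were Psmg4 (0.19), Sostdc1 (0.0854), Il4ra (-0.0494), Klrc2 (-0.48), Mcm5 (0.50), Hspa8 (0.0839), Crebbp (-0.12), Gapdh (0.34), Ldha (0.0784), Aldoa (0.0104), Atp5e (0.16), Uqcrh (0.0405), Cox8a (0.0350), Uty (-0.26) and Cd79b (-1.59). In ribosome-poor cells they were Rflnb (0.16), Ccr2 (-0.55), Gata3 (-0.0375), Tox2 (-0.0753), Cd160 (-0.44), Trgv2 (-0.30), 5830411N06Rik (-0.85), Hspa8 (0.0471), Crebbp (-0.0562), Asxl1 (-0.21), Atp5e (0.19), Uqcrh (0.10), Uty (-0.37), Cd79b (-0.40) and Klrb1c (-0.26). Under stricter filters Hspa8 was at 0.00029, Crebbp at -0.0113 and Cox8a at 0.0124, and in ribosome-rich cells Hspa8 at 0.00955, Crebbp at -0.0203 and Cox8a at 0.0411. Cd79b was at -0.0573 thinned and -0.11 under looser filters. Ralyl in CD4 memory or Tfh cells (-4.64) was at 3.08 in the CD4 gate.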

Other observations

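The results below come from tests chosen after the data were seen. Gh, the growth hormone gene (ENSMUSG00000020713, chromosome 11, 106300271 to 106301865, minus strand), is not known as a T cell gene, yet had 85 UMIs in 65 KO cells and 1 UMI in the WT library (313-fold, 54.6 to 1.25e+04), with at most 5 UMIs in 1 cell. It was spread over the classes, with 32 UMIs in CD4 naive-like, 21 in CD4 memory or Tfh-like, 23 in CD8-like and 7 in Treg-like KO cells, though only 5 of the 23 CD8-like UMIs lay outside the KO barcodes over 30000 UMIs. Ribosome-rich KO cells held 46 and ribosome-poor ones 39, and a further 72 lay in the KO barcodes that failed the filters, where the WT library had none. Whether these UMIs are expression of Gh, or come from another library or from a construct that carries part of its sequence, was not tested, so the fold is not a level of Gh expression.

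The 4 Ly49 genes named here, picked for their folds or as list members, lie on chromosome 6 and were higher in the KO library over all T cells. Klra8 (130115226 to 130129898) stood at 93.8-fold, Klra4 (130043731 to 130067271) at 36.5-fold, Klra1 (130363917 to 130386874) at 12.4-fold and Klra3 (130323289 to 130337574) at 11.2-fold. Within the KO library they did not share 1 class: Klra8 and Klra4 had 146 of 153 and 154 of 159 UMIs in CD8-like cells, while Klra1 had 182 of 269 UMIs in NKT-like cells and Klra3 was divided between both, with 65 and 82 of 155. Among CD8-like cells without barcodes over 30000 UMIs, Klra1 was about level (1.17-fold, 0.744 to 1.797). Of the 24 lists compared between CD8-like and conventional CD4-like cells, 0 had medians beyond their intervals in opposite directions. That comparison pools the CD4 naive-like and CD4 memory or Tfh-like classes and can hide differences. The cytotoxic median given above was lower in the KO library in CD8-like cells and higher in CD4 naive-like cells, beyond both intervals.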
